A study of Paralichthys olivaceus with 48 samples.

How the data were processed

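Spleen RNA of Japanese flounder was measured on 48 Agilent arrays with 1 dye (Cy3), on 6 slides of 8 arrays. The scanner files hold a spot intensity on a linear scale, made from the array images with Agilent Feature Extraction 10.7.3.1, per the file headers, while the submitters' processing notes name version 9.5.3.1. The column used is the processed signal, which Feature Extraction had corrected for background, per the file headers. Each file holds 15197 spots, of which 536 are controls. The deposited value table holds log2 values, whose scale and centring per probe were found by comparing it with the scanner files. The scanner log2 values minus the array's 75th percentile were set against the deposited ones, after the median difference of each array was removed. They differed by a constant within each probe, with a median SD over arrays of 3.9e-07 and a largest of 0.11. In the deposited table, 100% of the probes had a median over the 12 day 0 arrays of 0 within 1e-5. The medians of its columns ran from -0.149 to 0.255. The direction is that of the signal. The scaling between arrays in the deposited table was left open, because an offset shared by all probes of an array was removed in this comparison.

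The main value was log2 of the processed signal minus the array's 75th percentile over the non-control spots. Spots marked as outliers, 0.0668% of the readings, were left out, and 0 spots were saturated. Spots of a probe were averaged, which concerned 20 probes. Of 14481 probes, 14412 were well above background on at least 3 of the 48 arrays and were tested. Of the 14481, 14052 are named as JFC contigs, 17 as POC contigs and 412 by a sequence accession. None of these names was found in the reference gene table (assembly ASM2471397v2, 0 matches), so no gene name is used. The gene lists and single genes fixed for this study need gene names and were not tested.

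Groups were taken from the labels as the combination of temperature, injection and time, 16 groups of 3 arrays. One cell-means model over all 48 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 32 residual degrees of freedom), with version 1.17.8 of data.table for reading. The 20 contrasts were FKC against PBS at each temperature and time (8), 22 °C against 15 °C in PBS and in FKC fish at each time (8), and the difference of the FKC effect between the temperatures at each time (4). The p-values are two-sided, were adjusted by Benjamini-Hochberg within a contrast, and were called at 0.05 with no fold threshold. Where nothing differs, a share of 0.05 of the probes is expected at an unadjusted p under 0.05. The median SE of a log2 difference was 0.268, and 0.379 for the difference of differences, and the number of arrays limits this precision. Contigs were named by a fixed rule: at most 2 up and 2 down in a contrast, those with the largest log2 change among the called probes whose 3 arrays of one group all lay above the 3 of the other (for the difference of differences, called probes alone). A probe well above background on none of the 3 arrays of a group has only a bound there, and where some of the arrays measured it their number is given. The bound is given as "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. The groups, the contrasts, the test, the naming rule and the alternatives, apart from the 2 stated as added, were chosen before the data were examined. The normexp alternative departed from the plan, which named the mean signal where the median signal was used.

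The steps were tested on simulated data made from the real arrays' means and spread, with known changes in some of the 14412 probes. Each probe had its overall mean and independent noise, with no slide effect, atypical array or correlation between probes. The shares called therefore need not carry over to the real contrasts. For FKC against PBS at 22 °C and 6 h, 18.5%, 50% and 78.7% of the probes changed by 1.5, 2 and 4-fold were called, for 22 °C against 15 °C in PBS fish at 6 h 14.1%, 34.8% and 82.9%, and for the difference of the FKC effect at 6 h 3.12%, 24.6% and 71.6%.

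The slide is a batch: slides 1 to 3 hold the day 0 and 6 h arrays and slides 4 to 6 those of day 3 and day 28, and the 2 sets were scanned in separate sessions. No contrast between times was among those chosen, and between the 2 sets scan session and time cannot be told apart. Alternatives were quantile normalization, normexp background correction (offset 50) with the median signal and median background columns used here, no filter on dim probes or one of at least 24 arrays, slide as a fixed or random block, fits within a slide, the replicate number as a block, only the groups compared, the deposited table, and each array left out in turn. Some alternatives were added after the data were seen: leaving out 2 arrays that stood apart, and a replicate block over the compared groups alone. The replicate numbers were checked for pairing through the correlation of deviations from the group means. All 3 pairs were above 0.1 in 2 of 16 comparisons, FKC against PBS at 22 °C and day 28 and 22 °C against 15 °C in PBS fish at 6 h, and the labels give no shared source for a number. No 2 arrays were duplicates: the highest correlation between any 2 was 0.9895, and the lowest within a group was 0.907.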

Results

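Spleen RNA of the Japanese flounder (Paralichthys olivaceus, a marine flatfish) was measured on 48 one-colour Agilent arrays. The fish had been injected intraperitoneally with formalin-killed cells of Edwardsiella tarda (FKC), a Gram-negative bacterium that causes edwardsiellosis in cultured flounder, or with phosphate-buffered saline (PBS), and were reared at 15 °C or 22 °C. Spleens were taken at day 0, 6 h, day 3 and day 28, which gave 16 groups of 3 arrays. The labels did not state whether the 3 arrays of a group were single fish or pools, so the p-values measure the spread between these samples. The labels also did not state when the day 0 spleens were taken relative to the injection. Between 91.6% and 98.9% of the probes of an array were well above background, and the 75th percentile of the signal ranged from 453 to 1496. Values are log2 signal relative to that percentile, and the error of a log2 fold change is its standard error (SE) from the model with n = 3 arrays a group. Contigs are named as the array design names them, because the files pair no gene name with a probe. Whether named contigs share a transcript was not tested. Some of them, such as JFC03172_1_code and JFC00244_1_code, had near equal values in most groups, so they need not be separate signals.

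The first question was how the spleen of fish reared at 15 °C responded to FKC. At 6 h, 3980 of 14412 probes differed between FKC and PBS, 1239 higher and 2741 lower, and 1759 of them by at least 2-fold. JFC00907_1_code was 241-fold higher in FKC fish (log2 7.91 ± 0.69, adjusted p = 5.76e-11), at 6.66 ± 0.59 (SD, n = 3) against -1.26 ± 1.41 in PBS fish. JFC03540_2_code was 235-fold higher (log2 7.88 ± 0.71, adjusted p = 1.02e-10). JFC18735_1_code fell by 3.00 ± 0.23 on the log2 scale, or 8.01-fold (adjusted p = 1.81e-12), and JFC16209_1_code was 22.7-fold lower (log2 -4.50 ± 0.997, adjusted p = 0.000952). Each of these 4 contigs kept its call without any 1 of the 6 arrays. With slide as a fixed block the count was 364, 271 of them higher, the median SE was 0.47 in place of 0.27, the called probes kept 0.821 of their change as a median, and JFC16209_1_code stood at -1.58 ± 1.78 (adjusted p = 0.744). No slide held both groups at this time, and without PBS array 3 at 6 h the count was 1764, 847 higher and 917 lower. Normexp background correction called 857, 495 higher and 362 lower. Only the 2 groups compared gave 374, 321 of them higher, and leaving out PBS array 3 here and FKC array 3 at day 3 and 22 °C, the 2 arrays that stood apart, gave 1938.

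At day 3 and 15 °C, 4578 probes differed between FKC and PBS, 1399 higher and 3179 lower. EU224373 was 60.9-fold higher in FKC fish (log2 5.93 ± 0.55, adjusted p = 2.53e-09), and it had been 4.74 ± 0.55 higher at 6 h (adjusted p = 2.81e-08). JFC28092_1_code was 52.8-fold higher (log2 5.72 ± 0.85, adjusted p = 5.48e-06), with 1 of 3 PBS arrays well above background for it. JFC08424_1_code fell by 4.75 ± 0.89, or 26.9-fold (adjusted p = 0.000134). JFC06691_1_code was 186-fold lower (log2 -7.54 ± 2.17, adjusted p = 0.00819), with an SD of 3.36 among the PBS arrays, and lost its call without PBS array 1 (log2 -5.85, adjusted p = 0.0641). The median of all probes lay at -0.26, and at -0.072 under quantile normalization, which called 3440 probes, 1560 higher and 1880 lower, and normexp called 1275, 634 higher and 641 lower. With slide as a fixed block 3654 probes were called, 3475 of them among the 4578 and in the same direction, and 3274 within slide 4, which held FKC arrays 1 to 3 and PBS arrays 1 and 2.

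The probes called at 6 h and 15 °C were followed to the other times. The list was that of the main fit, and the steps were not redone without PBS array 3. Of the 1239 that were higher at 6 h, 476 were also higher at day 3 where independent lists would share 120.3, and of the 2741 that were lower, 1368 were also lower against 604.6. The medians of these sets were 0.40 and -0.64 at day 3, 0.0095 and 0.031 at day 28, and -0.079 and 0.21 between the groups labelled FKC and PBS at day 0, where 23.8% of the 2741 had a negative value. Between 6 h and day 3, 58 probes passed from higher to lower (273.3 for independent lists) and 24 from lower to higher (266.1), fewer than such lists would give. JFC00907_1_code was at 4.63 ± 0.69 at day 3 (adjusted p = 5.7e-06) and 3.01 ± 0.69 at day 28 (adjusted p = 0.0977).

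**Figure D1:**
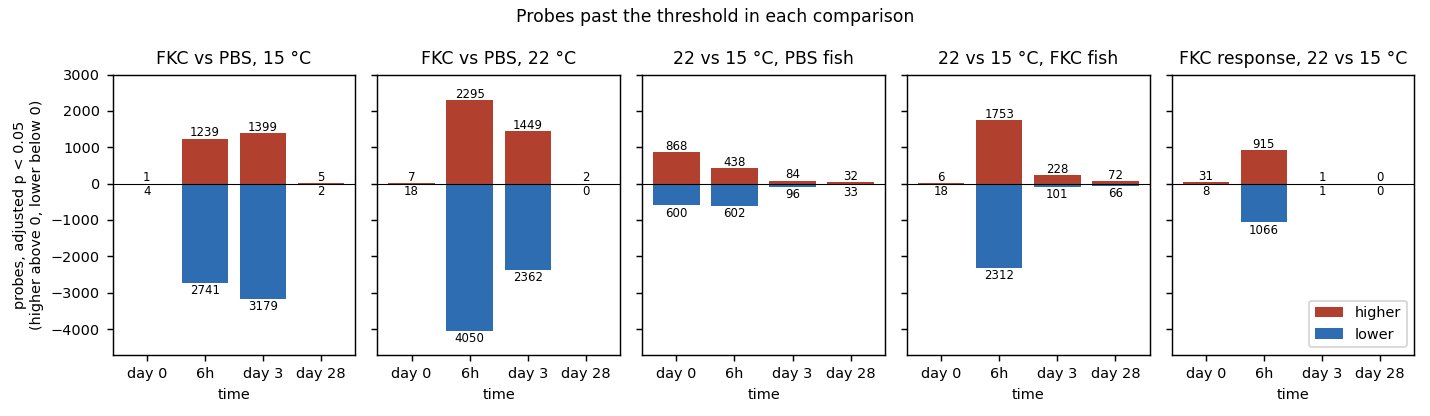
Number of probes past an adjusted p of 0.05 at each time for FKC against PBS at 15 °C and 22 °C, for 22 °C against 15 °C in PBS and in FKC fish, and for the difference of the FKC response between the temperatures; bars above 0 count probes that were higher and bars below 0 probes that were lower. FKC against PBS reached 3980 and 4578 probes at 6 h and day 3 at 15 °C and 6345 and 3811 at 22 °C, and at day 28 it reached 7 and 2.

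At day 28 and 15 °C, 7 probes passed the threshold, 5 higher and 2 lower in FKC fish. JFC06848_1_code was 5.12-fold higher (log2 2.36 ± 0.48, adjusted p = 0.0418) and JFC01134_1_code 4.08-fold higher (log2 2.03 ± 0.37, adjusted p = 0.0255). JFC00827_1_code was 4.28-fold lower (log2 -2.10 ± 0.42, adjusted p = 0.0418) and JFC04277_1_code 3.22-fold lower (log2 -1.69 ± 0.31, adjusted p = 0.0255). With slide as a fixed block limma called 0 probes, where 862 had an unadjusted p under 0.05 without it, no slide held both groups, and JFC00827_1_code stood at -0.24 ± 0.37 and JFC04277_1_code at -0.73 ± 0.40. The same model called 0 under normexp and 0 with only the groups compared, and 16 without the 2 arrays that stood apart. Without FKC arrays 1, 2 and 3 in turn the counts were 13, 3 and 2, and without PBS arrays 1, 2 and 3 they were 0, 0 and 19, and each of the 4 contigs lost its call in 3 to 6 of these 6 fits.

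At day 0 and 15 °C, 5 probes differed between the groups labelled FKC and PBS, 1 higher and 4 lower. JFC26843_1_code was 5.59-fold higher (log2 2.48 ± 0.44, adjusted p = 0.0223). JFC04800_1_code was 3.5-fold lower (log2 -1.81 ± 0.34, adjusted p = 0.0223) and JFC01299_1_code 3.25-fold lower (log2 -1.70 ± 0.32, adjusted p = 0.0223). Quantile normalization called 1 probe, which was higher, 4 were called from the deposited table, all lower, and limma called 0 with slide as a fixed block and 0 within slide 1, against 2193 at an unadjusted p under 0.05 without the block. In addition limma called 0 under normexp and 0 with only the groups compared, and 10 without the 2 arrays that stood apart. Without FKC arrays 2 and 3 the counts were 1 and 0, and without PBS arrays 1, 2 and 3 they were 15, 256 and 0, and each of the 3 contigs lost its call in 3 or 4 of the 6 fits without 1 array.

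The second question was how fish reared at 22 °C responded. At 6 h, 6345 probes differed between FKC and PBS, 2295 higher and 4050 lower, and 3521 of them by at least 2-fold. JFC03172_1_code was 743-fold higher in FKC fish (log2 9.54 ± 0.74, adjusted p = 8.2e-13) and JFC00244_1_code 704-fold higher (log2 9.46 ± 0.74, adjusted p = 1.06e-12). JFC20493_1_code fell by 5.48 ± 0.30, or 44.8-fold (adjusted p = 2.64e-16), from 3.57 ± 0.090 (SD, n = 3) in PBS fish to -1.92 ± 0.71. FJ211414 was 41.3-fold lower (log2 -5.37 ± 1.56, adjusted p = 0.00498), with an SD of 3.96 among the PBS arrays, and lost its call without PBS array 1 (log2 -3.09, adjusted p = 0.111). The median of all probes lay at -0.17, and at -0.042 under quantile normalization, with which 6188 probes were called, and normexp called 3090, 1367 higher and 1723 lower. In the fit with slide as a block 5617 probes were called, 5420 of them among the 6345 and in the same direction, and 3212 within slide 3, which held PBS arrays 1 to 3 and FKC arrays 2 and 3.

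At day 3 and 22 °C, 3811 probes differed, 1449 higher and 2362 lower in FKC fish. JFC28092_1_code was at least 68.1-fold higher (adjusted p = 3.45e-07), since it was not well above background on the PBS arrays. AB070835 was 47.3-fold higher (log2 5.56 ± 0.67, adjusted p = 2.96e-07), with 2 of 3 PBS arrays well above background for it. JFC01702_1_code was 35.5-fold lower (log2 -5.15 ± 1.43, adjusted p = 0.00791) and JFC23825_1_code 21.2-fold lower (log2 -4.41 ± 1.10, adjusted p = 0.00346), each well above background on 2 of 3 FKC arrays. Without FKC array 3 these 2 contigs stood at -2.91 (adjusted p = 0.132) and -1.37 (adjusted p = 0.0413). The median of all probes lay at -0.20, and at 0.014 under quantile normalization, which called 3269 probes, 1936 higher and 1333 lower, normexp 1050, 568 higher and 482 lower, and a fit of only the 2 groups 2291. With slides blocked, 64 probes were called, 52 of them higher, with a median SE of 0.47 and 0.828 of the change kept as a median. AB070835 kept its call in that fit, and JFC28092_1_code (adjusted p = 0.0635), JFC01702_1_code (-4.11 ± 2.69, adjusted p = 0.615) and JFC23825_1_code (-3.46 ± 2.10, adjusted p = 0.581) lost theirs. No slide held both groups, and without PBS array 1 the count was 2356.

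The probes called at 6 h and 22 °C were followed in the same way. Of the 2295 that were higher, 691 were higher at day 3 against 230.7 for independent lists, and of the 4050 that were lower, 942 were lower against 663.8. The medians of these sets were 0.25 and -0.29 at day 3, -0.038 and 0.0083 at day 28, and -0.025 and -0.094 at day 0. Between 6 h and day 3, 99 probes passed from higher to lower (376.1 for independent lists) and 277 from lower to higher (407.2). Such reversals were thus fewer than independent lists would give. JFC20493_1_code, the contig that fell by 5.48 at 6 h, stood at 0.15 ± 0.30 at day 3 (adjusted p = 0.743). JFC03172_1_code was still 4.47 ± 0.74 higher at day 3 (adjusted p = 2.91e-05), with 2 of 3 PBS arrays well above background for it, and stood at -0.96 ± 0.74 at day 28 (adjusted p = 1).

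**Figure D2:**
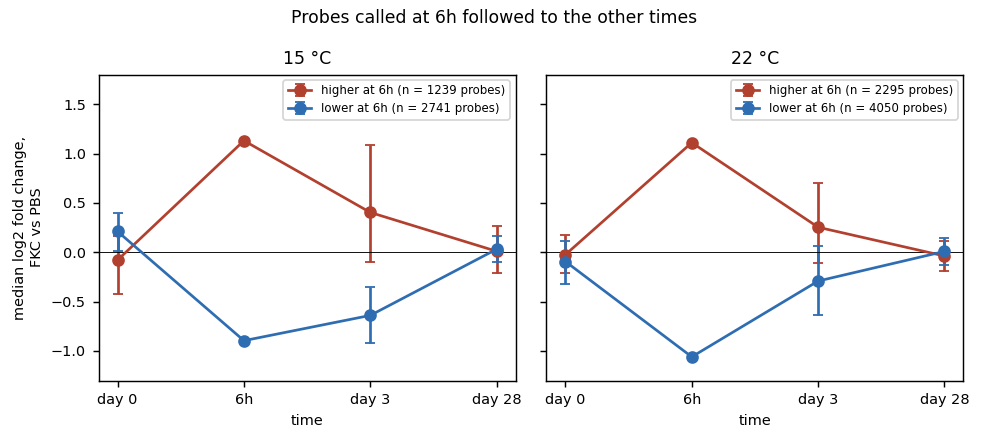
Median log2 fold change of FKC against PBS at each time for the probes called higher or lower at 6 h, at 15 °C (left) and 22 °C (right), with bars from the lower to the upper quartile of the probes at the times other than 6 h. The sets of 1239 and 2741 probes at 15 °C lay at 0.40 and -0.64 at day 3 and those of 2295 and 4050 probes at 22 °C at 0.25 and -0.29, and each set lay within 0.04 of 0 at day 28.

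At day 28 and 22 °C, 2 probes passed the threshold, both higher in FKC fish. JFC23726_1_code was 7.5-fold higher (log2 2.91 ± 0.53, adjusted p = 0.0251), and had been 5.18 ± 0.53 higher at 6 h and 2.74 ± 0.53 at day 3. JFC11043_1_code was 2.88-fold higher (log2 1.53 ± 0.25, adjusted p = 0.0105), after 2.52 ± 0.25 at 6 h and 1.72 ± 0.25 at day 3. Quantile normalization called 4 probes, 3 higher and 1 lower, and a fit of only the groups compared 2, both lower. Under a fixed slide block limma called 0. Without the block 615 had an unadjusted p under 0.05, fewer than the share of 0.05 expected where nothing differs. Within slide 6 limma called 2, both lower. Without FKC arrays 1, 2 and 3 in turn the counts were 0, 0 and 5, and without PBS arrays 2 and 3 they were 0 and 0, and the contigs lost their calls in 5 and 4 of the 6 fits.

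At day 0 and 22 °C, 25 probes differed between the groups labelled FKC and PBS, 7 higher and 18 lower. JFC26843_1_code was 4.85-fold higher (log2 2.28 ± 0.44, adjusted p = 0.0275), as it was at 15 °C, and JFC03856_1_code 2.05-fold higher (log2 1.03 ± 0.21, adjusted p = 0.0319). JFC00827_1_code was 5.86-fold lower (log2 -2.55 ± 0.42, adjusted p = 0.0086) and JFC19191_1_code 5.1-fold lower (log2 -2.35 ± 0.52, adjusted p = 0.0441). Normexp background correction placed JFC03856_1_code at -0.40 (adjusted p = 0.503), where the median of all probes lay at -0.637, against -0.0983 in the main fit. Limma called 0 probes with that correction, where 1915 had an unadjusted p under 0.05 without it. Quantile normalization called 32 probes, 22 higher and 10 lower. After blocking by slide 241 probes were called, 59 higher and 182 lower, of which 0 were among the 25 in the same direction, and no slide held both groups. The 25 probes kept 0.347 of their change as a median under that block, with JFC00827_1_code at -0.52 ± 0.37 (adjusted p = 0.477) and JFC19191_1_code at -0.84 ± 0.86 (adjusted p = 0.635). With only the groups compared 2 probes were called, and 95 without the 2 arrays that stood apart. Without FKC arrays 1, 2 and 3 in turn the counts were 7, 2 and 39, and without PBS arrays 1 and 2 they were 2 and 4; JFC26843_1_code, JFC03856_1_code and JFC19191_1_code lost their calls in 3, 4 and 6 of the 6 fits and JFC00827_1_code in none.

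The third question was whether the response to FKC differed between the temperatures, tested as the FKC effect at 22 °C minus that at 15 °C. At 6 h this difference passed the threshold for 1981 probes, 915 more positive and 1066 more negative at 22 °C. Normexp gave 507 probes, a fit of only the 4 groups 609, and leaving out PBS array 1 at 15 °C 1264 more positive and 1059 more negative. JFC00197_1_code rose with FKC at 15 °C, to 3.05 from 0.45 in PBS fish, and fell at 22 °C, to -0.56 from 1.59, a difference of -4.76 ± 0.49 (adjusted p = 2.95e-08). JFC28092_1_code rose at both temperatures, to -1.08 from -4.94 at 15 °C and to 2.42 from -5.76 at 22 °C (difference 4.33 ± 1.20, adjusted p = 0.013). JFC24582_1_code (4.25 ± 1.31, adjusted p = 0.0252) and FJ211416 (-9.34 ± 2.94, adjusted p = 0.0289) were more variable, with SDs of up to 2.30 and 5.14 within a group. JFC24582_1_code was well above background on 1 of 3 arrays in each PBS group and on 2 of 3 in FKC fish at 15 °C, and FJ211416 on 2 of 3 in FKC fish at 22 °C and in PBS fish at 15 °C. The contigs that led the 22 °C response also differed, JFC03172_1_code by 4.11 ± 1.04 (adjusted p = 0.00622) and JFC20493_1_code by -3.87 ± 0.43 (adjusted p = 1.01e-07), whereas JFC00907_1_code differed by -1.14 ± 0.98 (adjusted p = 0.52). When slide was a fixed block, 1446 probes passed, 1256 of them among the 1981 and in the same direction, in a fit where slides 2 and 3 are linked by FKC array 1 at 22 °C alone. Under that block JFC28092_1_code stood at 3.84 ± 1.41 (adjusted p = 0.0821), JFC24582_1_code at 1.68 ± 1.41 (adjusted p = 0.556) and FJ211416 at -8.68 ± 3.78 (adjusted p = 0.161), and they lost their calls in 1, 5 and 6 of the 12 fits without 1 array, the first without PBS array 1 at 15 °C (3.23, adjusted p = 0.054).

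Among the 1981 probes, the estimates had the same sign at both temperatures and were larger at 22 °C for 1107, were larger at 15 °C for 51 and had opposite signs for 823. Of these probes, 1341 passed the FKC test at 22 °C and not at 15 °C, 140 at 15 °C and not at 22 °C, and 462 at both, 53 of them in opposite directions. Across all 14412 probes the FKC effects at the 2 temperatures correlated at r = 0.689 at 6 h and 0.492 at day 3, where probes are not independent replicates. The lists of the 2 temperatures shared 884 probes that were higher at 6 h (197.3 for independent lists) and 1793 that were lower (770.3). Of the 2730 probes called at both temperatures at 6 h, 69.3% had the larger change at 22 °C, with a median size of 1.26 against 0.96 at 15 °C. The 6 h counts rest on the 15 °C list of 3980 probes, which fell to 1764 without PBS array 3 at 15 °C. The counts were not redone without that array. At day 3 the lists shared 897 probes that were higher (140.7 for independent lists) and 1084 that were lower (521), and 46.1% of the 1991 probes called at both had the larger change at 22 °C.

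**Figure D3:**
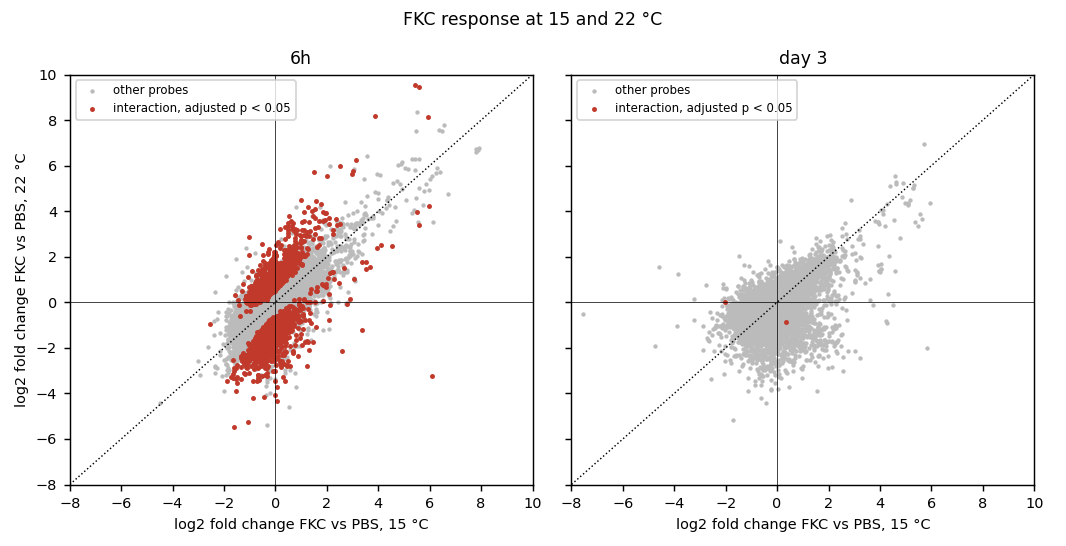
Log2 fold change of FKC against PBS at 22 °C (vertical axis) against that at 15 °C (horizontal axis) for each of 14412 probes at 6 h (left) and day 3 (right); red points passed the test of the difference between the temperatures at an adjusted p of 0.05 and the dotted line marks equal change. At 6 h 1981 probes passed, most of them with the larger change at 22 °C, and at day 3 2 probes passed.

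At day 3 the difference passed for 2 probes. JFC26554_1_code fell with FKC at 15 °C, to 3.41 from 5.42, and lay at 4.92 against 4.90 at 22 °C (difference 2.03 ± 0.32, adjusted p = 0.00174). JFC04561_1_code lay at -1.78 in FKC against -0.91 in PBS fish at 22 °C and at -0.93 against -1.26 at 15 °C (difference -1.20 ± 0.19, adjusted p = 0.00174). In the fit with slide as a block 1 probe passed, and JFC26554_1_code stood at 2.04 ± 0.41 (adjusted p = 0.126). Quantile normalization gave 9, a filter of at least 24 arrays 4, the replicate block 5, only the groups compared 8 and normexp 0, against 2048 at an unadjusted p under 0.05 in limma without it. Without FKC array 1 at 15 °C, PBS array 3 at 15 °C, FKC array 1, FKC array 2 and PBS array 1 at 22 °C the counts were 15, 31, 26, 21 and 4.

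At day 28 limma called 0 probes for the difference. An unadjusted p under 0.05 was reached by 541, fewer than the share of 0.05 expected where nothing differs. For the groups labelled FKC and PBS at day 0 it called 39, 31 more positive and 8 more negative at 22 °C, led by JFC04395_1_code (2.75 ± 0.61, adjusted p = 0.0392), JFC23320_1_code (2.21 ± 0.46, adjusted p = 0.0341), JFC13684_1_code (-2.40 ± 0.52, adjusted p = 0.0385) and JFC03138_1_code (-1.38 ± 0.26, adjusted p = 0.0245). All 39 had opposite signs at the 2 temperatures, 3 passed for FKC against PBS at 22 °C alone and 1 at 15 °C alone, and 37 were also called for 22 °C against 15 °C in PBS fish, which uses the same PBS arrays. With slides blocked, the day 0 count was 1389, under quantile normalization 82 and without the 2 arrays that stood apart 429 (176 more positive and 253 more negative). Normexp and only the groups compared gave 0 and 0, against 2422 at an unadjusted p under 0.05 in limma without these changes. Without FKC array 3 and PBS arrays 1, 2 and 3 at 15 °C it was 1, 4, 322 and 3, without FKC arrays 1 and 3 at 22 °C 0 and 96, and without PBS arrays 1, 2 and 3 at 22 °C 0, 24 and 79, and each of the 4 contigs lost its call in 4 to 7 of the 12 fits without 1 array.

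The fourth question was how rearing temperature alone changed the spleen, compared in PBS fish. At day 0, 1468 probes differed between 22 °C and 15 °C, 868 higher and 600 lower at 22 °C, and 502 by at least 2-fold. JFC06316_1_code was 5.01-fold higher at 22 °C (log2 2.33 ± 0.60, adjusted p = 0.0116) and JFC28712_1_code 4.77-fold higher (log2 2.25 ± 0.61, adjusted p = 0.0162). JFC06329_1_code was at least 10.3-fold lower (adjusted p = 0.00394), as it was not well above background on the 22 °C arrays, and JFC08316_1_code was 10.5-fold lower (log2 -3.39 ± 0.75, adjusted p = 0.00375). Under a fixed slide block 2035 probes were called, 894 of them among the 1468 and in the same direction, JFC06316_1_code stood at 2.37 ± 0.88 (adjusted p = 0.0649), and JFC28712_1_code at 0.93 ± 0.81 (adjusted p = 0.454), the latter having lost its call in 2 of the 6 fits without 1 array. Within slide 2, which held 1 of the 15 °C arrays, 161 were called, and without PBS arrays 1 and 2 at 22 °C the counts were 604 (237 higher and 367 lower) and 949. Quantile normalization called 732 higher and 714 lower, normexp 29 higher and 60 lower, and a fit of only the groups compared 14 higher and 25 lower.

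At 6 h, 1040 probes differed between the PBS groups, 438 higher and 602 lower at 22 °C. JFC22320_1_code was 6.61-fold lower at 22 °C (log2 -2.73 ± 0.66, adjusted p = 0.00904) and JFC17857_1_code 5.69-fold lower (log2 -2.51 ± 0.55, adjusted p = 0.00416), the latter at -1.53 (adjusted p = 0.0401) without PBS array 3 at 15 °C. FJ211414 was 40.6-fold higher (log2 5.34 ± 1.56, adjusted p = 0.0314) and JFC00929_1_code at least 23.4-fold higher (adjusted p = 0.0291), with SDs of 3.96 and 3.95 among the 22 °C arrays, and without PBS array 1 at 22 °C they had adjusted p of 0.259 and 0.274, FJ211414 at a log2 of 3.07. Of the 868 probes higher at day 0, 136 were also higher at 6 h (26.38 for independent lists), and of the 600 lower ones 112 were lower (25.06). Quantile normalization called 1409 probes, 758 higher and 651 lower, slide as a fixed block 1260, and a fit of slide 3, which held all 6 arrays, called 3. Normexp called 127, 50 higher and 77 lower, and with only the groups compared limma called 0, where 3450 had an unadjusted p under 0.05 over all groups. Leaving out the 2 arrays that stood apart gave 1839. Without PBS arrays 1 and 3 at 15 °C the counts were 1609 and 1755, and without PBS arrays 1, 2 and 3 at 22 °C they were 647, 606 and 484.

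At day 3, 180 probes differed between the PBS groups, 84 higher and 96 lower at 22 °C. JFC04119_1_code was 9.41-fold higher (log2 3.23 ± 0.78, adjusted p = 0.0265) and JFC27846_1_code at least 2.14-fold higher (adjusted p = 0.0487), with 2 of 3 arrays well above background at 22 °C. JFC02701_1_code was 5.02-fold lower (log2 -2.33 ± 0.43, adjusted p = 0.00338) and JFC11526_1_code 6.46-fold lower (log2 -2.69 ± 0.60, adjusted p = 0.0177). After blocking by slide 5 probes were called, none of the 4 contigs among them (JFC02701_1_code -2.09 ± 0.57, adjusted p = 0.426, JFC04119_1_code 2.72 ± 1.13, adjusted p = 0.86, JFC11526_1_code -2.35 ± 0.82, adjusted p = 0.676, JFC27846_1_code adjusted p = 0.755). Quantile normalization called 342, normexp 17, only the groups compared 22, and leaving out the 2 arrays that stood apart 494. Within slide 5, which held 1 of the 15 °C arrays, limma called 0, where 2222 had an unadjusted p under 0.05 over all slides. Without PBS arrays 1 and 2 at 15 °C the counts were 34 and 39, and without PBS arrays 1 and 2 at 22 °C they were 112 and 48; JFC02701_1_code kept its call in each of these 6 fits without 1 array, and the other contigs lost theirs in 4 to 6.

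At day 28, 65 probes differed between the PBS groups, 32 higher and 33 lower at 22 °C. JFC07795_1_code was 7.81-fold higher (log2 2.97 ± 0.52, adjusted p = 0.0028) and JFC18918_1_code 5.08-fold higher (log2 2.35 ± 0.42, adjusted p = 0.00401). JFC00756_1_code was 5.66-fold lower (log2 -2.50 ± 0.60, adjusted p = 0.0432) and JFC15856_1_code 3.16-fold lower (log2 -1.66 ± 0.39, adjusted p = 0.0396). When slide was a fixed block, 62 probes were called, JFC00756_1_code with an adjusted p of 0.0503, and 23 within slide 6, which held all 6 arrays. Only the groups compared gave 9, leaving out the 2 arrays that stood apart 99, and normexp 0, where 1212 had an unadjusted p under 0.05 in limma without it. Without PBS arrays 1, 2 and 3 at 15 °C the counts were 30, 18 and 16, and without PBS arrays 1 and 2 at 22 °C they were 15 and 11; the 2 higher contigs lost their calls in 1 of the 6 fits and the 2 lower ones in 5 and 6.

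The same comparison in FKC fish was largest at 6 h, where 4065 probes differed between the temperatures, 1753 higher and 2312 lower at 22 °C. JFC06955_1_code was 13.5-fold lower at 22 °C (log2 -3.76 ± 0.28, adjusted p = 8.95e-12), and stood at -0.073 ± 0.28 in PBS fish (adjusted p = 0.902). JFC06329_1_code was at least 8.69-fold lower (adjusted p = 0.00422). JFC07019_1_code was 15.3-fold higher (log2 3.94 ± 1.17, adjusted p = 0.011), with 1 of 3 arrays well above background at 15 °C, and JFC21461_1_code 14.7-fold higher (log2 3.88 ± 1.33, adjusted p = 0.0274). JFC21461_1_code lost its call without any of 5 of the 6 arrays, with an adjusted p of up to 0.103, and JFC07019_1_code without FKC array 2 at 15 °C (adjusted p = 0.0688). The median of all probes lay at -0.12, and at 0.010 under quantile normalization, which called 3822 probes, 2105 higher and 1717 lower, and normexp called 1384, 673 higher and 711 lower. In the fit with slide as a block 1827 probes were called, 1711 of them among the 4065 and in the same direction, with 662 within slide 2, which held 1 of the 22 °C arrays, and the count without FKC array 2 at 22 °C was 2534. Under that block JFC06329_1_code had an adjusted p of 0.151, JFC07019_1_code stood at 4.73 ± 1.73 (adjusted p = 0.0691) and JFC21461_1_code at 4.05 ± 1.98 (adjusted p = 0.202).

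At day 3, 329 probes differed between FKC fish at 22 °C and 15 °C, 228 higher and 101 lower at 22 °C. AB191200 was 6.44-fold higher (log2 2.69 ± 0.70, adjusted p = 0.0306) and GU191337 6.08-fold higher (log2 2.60 ± 0.72, adjusted p = 0.0449), and each lost its call without any of 5 of the 6 arrays. FJ211416 was 356-fold lower (log2 -8.48 ± 2.08, adjusted p = 0.0237), with 2 of 3 arrays well above background at 22 °C, and JFC14470_1_code 116-fold lower (log2 -6.86 ± 1.93, adjusted p = 0.0481), with SDs of 3.83 and 2.60 among the 15 °C arrays, and they lost their calls in 3 and 5 of the 6 such fits. With slides blocked, 382 probes were called, and 1 within slide 4, which held all 6 arrays. Normexp called 41, leaving out the 2 arrays that stood apart gave 88, and with only the groups compared limma called 0, where 2347 had an unadjusted p under 0.05 over all groups. Without FKC arrays 1, 2 and 3 at 15 °C the counts were 120, 150 and 174, and without FKC arrays 1, 2 and 3 at 22 °C they were 602 (253 higher and 349 lower), 667 (326 higher and 341 lower) and 59.

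At day 28, 138 probes differed between FKC fish at the 2 temperatures, 72 higher and 66 lower at 22 °C. JFC01796_1_code was 4.39-fold higher (log2 2.13 ± 0.42, adjusted p = 0.00497) and JFC20747_1_code 4.15-fold higher (log2 2.05 ± 0.43, adjusted p = 0.00923). JFC20450_1_code was 19.1-fold lower (log2 -4.26 ± 0.88, adjusted p = 0.0088), with 1 of 3 arrays well above background at 22 °C, and GQ414990 38.2-fold lower (log2 -5.26 ± 1.35, adjusted p = 0.0464), with 2 of 3 arrays well above background at 22 °C and an SD of 2.93 among the 15 °C arrays. Under a fixed slide block 6 probes were called, none of the 4 contigs among them (JFC01796_1_code 2.46 ± 0.62, adjusted p = 0.133, JFC20747_1_code 2.35 ± 0.61, adjusted p = 0.14, JFC20450_1_code -3.28 ± 1.25, adjusted p = 0.467, GQ414990 -4.50 ± 2.01, adjusted p = 0.595). Within slide 5, which held 1 of the 22 °C arrays, limma called 0, where 1633 had an unadjusted p under 0.05 over all slides. With only the groups compared limma also called 0, and it called 14 under normexp and 242 without the 2 arrays that stood apart (110 higher and 132 lower). Without FKC arrays 2 and 3 at 15 °C the counts were 85 and 46, and without FKC arrays 1, 2 and 3 at 22 °C they were 44, 52 and 85, and the 4 contigs lost their calls in 1 to 5 of the 6 fits.

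At day 0, 24 probes differed between the groups labelled FKC at the 2 temperatures, 6 higher and 18 lower at 22 °C. JFC14084_1_code was 3.12-fold lower at 22 °C (log2 -1.64 ± 0.21, adjusted p = 1.89e-05) and JFC11204_1_code 3.44-fold lower (log2 -1.78 ± 0.34, adjusted p = 0.0131). JFC17905_1_code was 2.32-fold higher (log2 1.22 ± 0.24, adjusted p = 0.0166). JFC02713_1_code was higher at 22 °C (adjusted p = 3.05e-05) but was well above background on 1 of the 6 arrays, so no fold is given. After blocking by slide 21 probes were called, and within slide 1, which held all 6 arrays, limma called 0, where 1156 had an unadjusted p under 0.05 over all slides. With only the groups compared limma also called 0, and it called 1 under normexp and 57 without the 2 arrays that stood apart. Without FKC arrays 2 and 3 at 15 °C the counts were 13 and 5, and without FKC arrays 2 and 3 at 22 °C they were 7 and 14, and JFC17905_1_code and JFC11204_1_code lost their calls in 3 of the 6 fits.

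**Figure D4:**
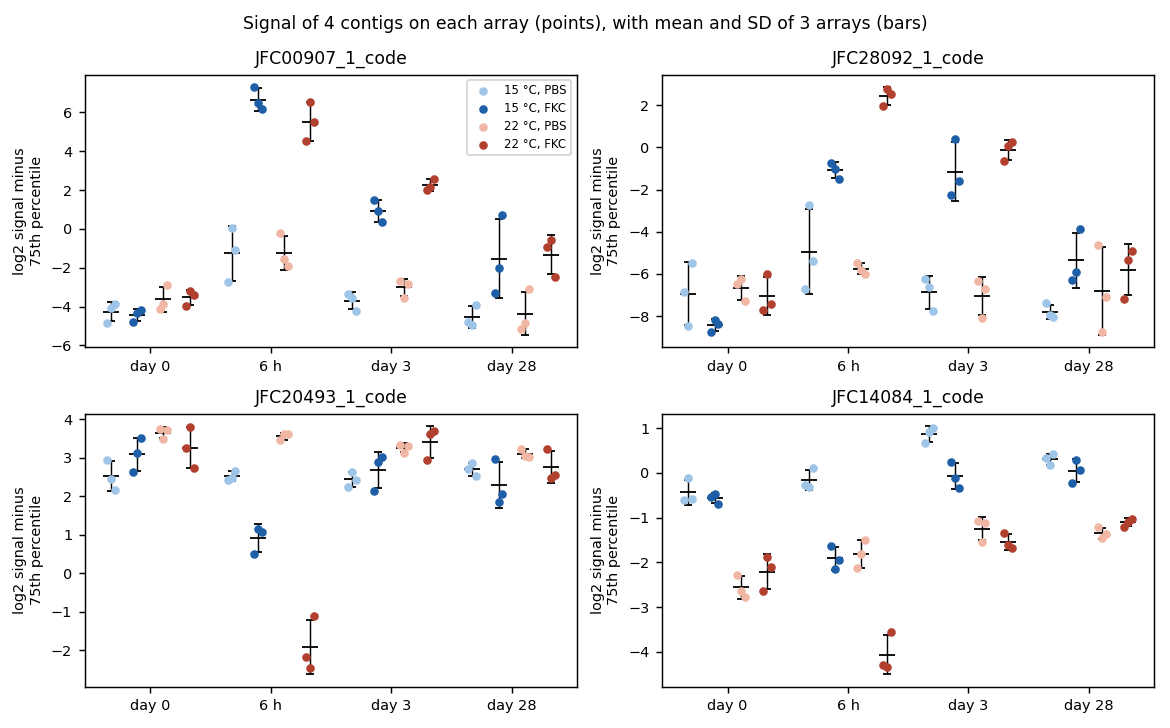
Log2 signal minus the array's 75th percentile (vertical axes) of 4 contigs on each array (points), by time, temperature and injection, with the mean and SD of 3 arrays (bars). JFC00907_1_code and JFC28092_1_code were higher in FKC fish at 6 h and day 3, JFC20493_1_code was lower in FKC fish at 6 h, and JFC14084_1_code was lower at 22 °C than at 15 °C in both injections.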

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

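Some tests here were chosen after the result was seen. They were the slide tests, the comparison with FKC fish at day 0, the test of PBS array 1 at day 0, and the brightness and spike-in tests of array 3. So were the exchanges of temperature labels, the sorting of divisions by their FKC arrays and the choice of divisions that part the replicate pairs. The other tests here were fixed earlier.

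The difference between FKC and PBS fish differed between 22 °C and 15 °C in a test of that difference for 1981 probes at 6 h, 39 at day 0 and 2 at day 3. At day 0 it is a difference between groups labelled FKC and PBS: all 39 had opposite signs at the 2 temperatures, 3 passed for FKC against PBS at 22 °C alone and 1 at 15 °C alone, and 37 were also called for 22 °C against 15 °C in PBS fish, which uses the same PBS arrays. At 6 h the named contigs were JFC28092_1_code (4.33), JFC24582_1_code (4.25), FJ211416 (-9.34) and JFC00197_1_code (-4.76), at day 0 JFC04395_1_code (2.75), JFC23320_1_code (2.21), JFC13684_1_code (-2.40) and JFC03138_1_code (-1.38), and at day 3 JFC26554_1_code (2.03) and JFC04561_1_code (-1.20), each as the log2 FKC effect at 22 °C minus that at 15 °C.

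The 6 h difference, by which JFC00197_1_code rose with FKC at 15 °C and fell at 22 °C, was set against 3 technical explanations. A difference between slides cannot be told apart from it, because at 15 °C the FKC arrays lay on slide 2 and the PBS arrays on slide 3 and 1 FKC array at 22 °C links these slides, although with slide as a block the 1981 probes kept 1.05 of their difference as a median (quartiles 0.934 and 1.17). A single atypical array is argued against, since 1993 probes passed without PBS array 3 at 15 °C and at least 1353 without any 1 of the 12 arrays. The scaling between arrays is argued against, since under quantile normalization the probes kept 0.94 of the difference (quartiles 0.889 and 0.993). A chance division of the arrays stays open as well. The 9 of 100 exchanges that gave as many, the real one included, all left the FKC arrays at their temperature and so kept their temperature difference. A dependence of the early spleen response on rearing temperature also stays open. The tested difference measures it, but no test set it apart from the slides.

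For the 6 h difference, 11 of 100 drawn divisions of the 12 arrays into 4 groups of 3 gave as many probes as the real one (1981, highest other 4969), so chance is not excluded by that count. A division adds the values of 6 arrays and subtracts those of 6, and the real one has 3 FKC arrays on each side. Of the 42 divisions with that balance 2 gave as many, the real one included (highest other 2351), of the 48 that were 1 FKC array off it 2 (highest 2773), and of the 10 that were 2 off it 7 (highest 4969), which points to the FKC difference as a structure of the samples. When temperature labels were exchanged within FKC arrays and within PBS arrays, 9 of 100 drawn exchanges gave as many (highest other 4083). All 9 were among the 13 that left the FKC arrays at their temperature, and 0 of the 87 that moved FKC arrays did (highest 589). At day 0 the numbers were 16 of 100 divisions (real count 39, highest other 1668) and 14 of 100 exchanges (highest other 761), and at day 3 23 of 100 (real count 2, highest other 3982) and 10 of 100 (highest other 79), so chance is not excluded at these times either. At day 28 the real count was 0, which any division reaches, so the 100 of 100 there decides nothing (highest other 97). The highest count at day 0 came from a division with the real balance, and that at day 3 from one 2 FKC arrays off it, so structure in the samples other than the tested difference is present at both times.

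The 1468 probes that differed between 22 °C and 15 °C in PBS fish at day 0, among them JFC06316_1_code and JFC08316_1_code, were the second pattern. A temperature difference shared by all day 0 fish is argued against for most of these probes, since the difference of FKC fish was 0.0771 of that of PBS fish as a median (quartiles -0.113 and 0.34). The probes were chosen by their difference in PBS fish, which can lower this ratio. A shared part was present among the 24 probes called in FKC fish. Of these, 5 of the 6 higher and 10 of the 18 lower were called in the same direction in PBS fish (0.3614 and 0.7494 for independent lists). PBS array 3 at 15 °C as the single cause is argued against, since 1002 probes were called without it, whereas PBS array 1 at 22 °C stays open, since 604 were called without it, 237 higher and 367 lower. A difference between slides cannot be told apart from the group difference, because slide 2 held 1 of the 15 °C arrays, although there the difference was 1.21 of its full value (quartiles 0.978 and 1.46). A biological difference between the PBS groups stays open as untested.

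PBS array 3 at 6 h and 15 °C stood apart from its group, with a root mean square deviation of 0.76 on the log2 scale and correlations of 0.907 to 0.929 with the other 2 arrays. An exchange of labels with an FKC fish is argued against, since its deviation followed the FKC change at 22 °C with a slope of -0.219 over the probes called there. A dim hybridisation is argued against, since the 75th percentile of its signal was 1077, against 453 to 1496 on the other arrays. A deviation shared with FKC array 3 at day 3 and 22 °C, the other array that stood apart (0.718), is argued against by a correlation of 0.0392 across probes. A technical difference other than dimness stays open, as its spike-in mean of 1.57 (0.773 and 0.986 in its group) was the highest of the 48 arrays. Its deposited median of 0.255 was also the highest, but PBS array 1 at 22 °C and day 3 lay close to it at 0.247. No biological explanation was tested, as the design gives none for a single array.

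The comparisons of 3 arrays with 3 have 10 divisions each, too few for a share under 0.05, so real counts are set beside the highest of the other divisions. For FKC against PBS at 15 °C these were 5 and 1 at day 0, 3980 and 1238 at 6 h, 4578 and 8 at day 3 and 7 and 0 at day 28, and at 22 °C 25 and 8, 6345 and 9, 3811 and 1, and 2 and 1. For 22 °C against 15 °C in PBS fish they were 1468 and 116 at day 0, 1040 and 1559 at 6 h, 180 and 0 at day 3 and 65 and 0 at day 28, and in FKC fish 24 and 9, 4065 and 109, 329 and 1, and 138 and 0. In PBS fish at 6 h 2 of the 10 divisions gave as many probes as the real one, the other joining array 1 at 22 °C to arrays 1 and 2 at 15 °C, with all 6 arrays on slide 3. Among the 4 divisions there that part all 3 replicate pairs, the real one called 1040 and the highest other 4, and for FKC against PBS at 22 °C and day 28 2 and 0. The pairs were inferred from correlations in these same arrays, and the division with 1559 is not among the 4. With 4 divisions no share under 0.05 can be reached, so these counts decide nothing about chance.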

How the results depend on the processing

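Leaving out the 2 arrays that stood apart and the replicate block over the compared groups alone were chosen after the data were seen. The other alternatives were planned, except that normexp was planned with the mean signal and run with the median signal. Of 71 results for named contigs, 12 kept direction and call under each alternative run, 27 kept their call in each fit without 1 array, 66 under quantile normalization, 29 under normexp, 36 with slide as a fixed block, 61 with it as a random block, 64 with the replicate block and 64 with the deposited table. JFC03856_1_code, FKC against PBS at 22 °C and day 0, reversed under normexp, to -0.401. The median of all probes in that contrast lay at -0.637 under normexp, against -0.0983 in the main fit. The counts stayed within 1.5 times with no filter on dim probes and with the deposited table for each of the 20 contrasts. Where no construction is named, the cause was not tested. Signal over background limits the dim contigs, of which the bounds above are examples; between 91.6% and 98.9% of probes were well above it.

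Quantile normalization moved the counts to 1 for FKC against PBS at 15 °C and day 0, 4 at 22 °C and day 28, 342 for 22 °C against 15 °C in PBS fish at day 3, and 82 and 9 for the difference of the FKC effect at day 0 and day 3. Normexp gave, for FKC against PBS at 15 °C, 0, 857, 1275 and 0 from day 0 to day 28, and at 22 °C 0, 3090 and 1050 from day 0 to day 3. For 22 °C against 15 °C it gave 89, 127, 17 and 0 in PBS fish and 1, 1384, 41 and 14 in FKC fish, and for the difference of the FKC effect 0, 507 and 0 from day 0 to day 3. Normexp also shifted the median of all probes. For FKC against PBS that median lay at -0.637 at 22 °C and day 0 and at 0.37 at 15 °C and day 28. Probes well above background on at least 24 arrays gave 4 for that difference at day 3.

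Slide as a fixed block gave, for FKC against PBS, 0, 364 and 0 at 15 °C at day 0, 6 h and day 28, and 241, 64 and 0 at 22 °C at day 0, day 3 and day 28. It gave 5 in PBS fish at day 3 and 1827 and 6 in FKC fish at 6 h and day 28 for 22 °C against 15 °C, and 1389 and 1 for the difference at day 0 and day 3. Where the compared groups lay on different slides, as for FKC against PBS at 15 °C and 6 h, the median SE grew from 0.268 to 0.467. As a random block, with a correlation of 0.0842 within a slide, it gave 0 for FKC against PBS at 15 °C and day 28, 0 at 22 °C and day 0, 106 for the temperatures in PBS fish at day 3 and 91 in FKC fish at day 28. Within a slide, with fewer arrays, the counts were 0 on slide 1 and 3212 on slide 3 for FKC against PBS at 15 °C and day 0 and at 22 °C and 6 h. For 22 °C against 15 °C they were 161, 3, 0 and 23 in PBS fish from day 0 to day 28 and 0, 662, 1 and 0 in FKC fish.

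The replicate block gave 5 in place of 2 for the difference of the FKC effect at day 3 and moved no other count by over 1.5 times. In the 2 comparisons whose pairs correlate, a block over the compared groups alone gave 1292 for the temperatures in PBS fish at 6 h and 3 for FKC against PBS at 22 °C and day 28.

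A fit of only the groups compared, with fewer arrays, gave for FKC against PBS 0, 374 and 0 at 15 °C at day 0, 6 h and day 28, and 2 and 2291 at 22 °C at day 0 and day 3. For the temperatures it gave 39, 0, 22 and 9 in PBS fish from day 0 to day 28 and 0, 0 and 0 in FKC fish at day 0, day 3 and day 28, and for the difference 0, 609 and 8 from day 0 to day 3. Without the 2 arrays that stood apart, PBS array 3 at 6 h and 15 °C and FKC array 3 at day 3 and 22 °C, FKC against PBS gave 10, 1938 and 16 at 15 °C at day 0, 6 h and day 28 and 95 at 22 °C and day 0. The temperatures gave 1839, 494 and 99 in PBS fish from 6 h to day 28 and 57, 88 and 242 in FKC fish at day 0, day 3 and day 28, and the difference gave 429 at day 0.

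The balance of higher and lower probes turned in some fits. Only the groups compared gave 321 higher and 53 lower for FKC against PBS at 15 °C and 6 h, and 14 and 25 for the temperatures in PBS fish at day 0. Without the 2 arrays that stood apart the difference of the FKC effect at day 0 had 176 higher and 253 lower. Without PBS array 3 at 15 °C the temperatures in PBS fish at day 3 gave 114 higher and 86 lower, and those at day 28 gave 30 and 16 without PBS array 3 at 22 °C and 29 and 23 with the replicate block. The difference of the FKC effect at 6 h had 1264 higher and 1059 lower without PBS array 1 at 15 °C. Smaller turns were 334 higher and 313 lower for the temperatures in PBS fish at 6 h without PBS array 1 at 22 °C, and 21 and 18 at day 3 without PBS array 2 at 15 °C. In FKC fish at day 28 there were 110 higher and 132 lower without the 2 arrays that stood apart, and 39 and 46 without FKC array 2 at 15 °C.

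With each array left out in turn, FKC against PBS at 15 °C ran from 0 to 256 at day 0, 1764 to 5278 at 6 h, 3124 to 4200 at day 3 and 0 to 19 at day 28. At 22 °C it ran from 2 to 39, 5330 to 6085, 2356 to 3371 and 0 to 5. For the temperatures the ranges were 604 to 1441, 484 to 1755, 34 to 200 and 11 to 46 in PBS fish and 5 to 30, 2534 to 3800, 59 to 667 and 44 to 138 in FKC fish. The difference of the FKC effect ran from 0 to 322, 1353 to 2323, 2 to 31 and 0 to 1.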

Other observations

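The contigs given here were chosen after their values were seen. A set of 713 probes was called for FKC against PBS at both 6 h and day 3 and at both temperatures, of which 303 were higher in all 4 comparisons, 378 lower in all 4 and 32 mixed. The list at 6 h and 15 °C that enters it fell from 3980 to 1764 without PBS array 3. The set was not redone without that array. AB198061 was 4.92 ± 0.59 higher at 6 h and 5.27 ± 0.59 at day 3 at 15 °C, and 6.15 ± 0.59 and 5.03 ± 0.59 higher at 22 °C. At day 28 it stood at 2.30 (adjusted p = 0.167) and 1.71 (adjusted p = 0.693). AY533022 gave 4.90, 5.34, 6.07 and 5.14 in the same order. JFC03035_1_code fell, with -1.88 ± 0.37 and -2.31 ± 0.37 at 15 °C and -2.96 ± 0.37 and -1.35 ± 0.37 at 22 °C.

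Some contigs differed between the rearing temperatures in each of the 8 groups of injection and time, 1 of them higher at 22 °C and 4 lower. FJ390056 was higher at 22 °C by 0.945 to 1.89 (mean 1.40). JFC14084_1_code was lower, with differences from -2.15 to -1.16 (mean -1.75), and fell with FKC at 6 h, with -1.75 ± 0.21 at 15 °C and -2.25 ± 0.21 at 22 °C. JFC20104_1_code was lower, with differences from -1.84 to -0.748 (mean -1.17). In at least 4 of the 8 groups, 22 probes were higher and 43 lower at 22 °C, and 17 differed in mixed directions.

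Among the 12116 probes well above background on all 48 arrays, the median SD within a group was 0.306, and the 50 most variable had SDs of 1.51 to 3.51. Of these 50, 44 were called in none of the 16 comparisons of 2 groups. The SD by which they were chosen also enters the test, so few calls follow from the choice. JFC23171_1_code had an SD of 3.51 and ran from -6.35 to 3.77 over the arrays, BR000406 from -5.53 to 5.54, and AF016922 from -3.71 to 7.29. The median correlation between pairs of the 50, after removal of group means, was 0.192, against 0.0171 for random probes.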
